A study of Danio rerio with 2 samples.

How the data were processed

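Single-cell RNA sequencing of pharyngeal arches and adjoining tissue was done on zebrafish (Danio rerio, strain AB) at 26 hours post fertilization. There were 2 libraries, 1 of wild-type embryos and 1 of nkx2.7-/- embryos, and each pooled 2 genotyped siblings from a cross of heterozygotes. A tcf21 reporter transgene guided the dissection, liberase was used to dissociate the tissue, and live nucleated cells were sorted on DAPI and DRAQ5. The sort selects on viability and not on the reporter, so every cell type of the dissected tissue can be present.

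The values deposited by the authors for each library are raw UMI counts per gene and barcode, a count matrix that Cell Ranger 6.1.2 made against GRCz11, per the submitters' processing notes. Each matrix has 25107 features that carry 24470 gene symbols, and features with a shared symbol were summed. The deposited cell table of the authors gives each kept cell's library, cluster number, cell type name, UMI count and detected gene count, and its mitochondrial fraction, a fraction of the cell's UMIs. The UMI counts and the mitochondrial fractions in that table equalled those recomputed from the matrices for all 12147 kept cells. Every kept cell had less than 20% mitochondrial UMIs. The authors' normalization, integration and cluster resolution are not given in the sources used here, and neither is any doublet removal. No doublets were called here either; leaving out the 5% of cells with the highest UMI count in each library stands in for that step among the alternatives.

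Each library's UMIs were summed over the cells of each of the 16 deposited cell types and scaled to the total UMIs of the class (counts per 1e6 UMIs, CPM), with no pseudocount. The mutant to wild-type CPM ratio has an exact conditional binomial (Clopper-Pearson) 95% interval, each CPM an exact Poisson interval, and each share of cells an exact binomial interval. These intervals cover counting error only. With 1 library per genotype there is no replicate spread, so no test, p-value or count of changed genes was made, and cells were not treated as replicates. A count of 0 was set to a floor of 3 counts for a limit. Classes were compared when both libraries held at least 50 cells. The median log2 ratio over all genes was between -0.03 and 0.08 in the compared classes, so no further scaling was applied.

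The cell types were checked against 21 marker lists written before the data were examined, as were the choices of comparisons, gene lists and most other settings. The 10 genes that led each class over the other classes were matched with these lists. Of the 3 main classes, cranial neural crest (cluster 4) had 9 leading genes on the arch neural crest list. Pharyngeal mesenchyme had 1 on its list and is called cluster 2 here, and pharyngeal endoderm had 0 on its list against 3 on the epidermis list and is called cluster 7 here. Names of the other classes are the authors'.

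Named genes follow a rule. For all kept cells and for each main class, genes needed at least 50 UMIs in both libraries together, at least 50 CPM in the higher library, the same direction under total-count and median-of-ratios scaling, and a symbol that is no clone name. The 12 highest and the 12 lowest ratios, ranked by the interval bound nearest to 1, were taken, plus nkx2.7 and up to 4 members per gene list with the largest such bound. Class-leading genes were not reported as results of their class unless the cells had also been grouped without them. Mitochondrially encoded, ribosomal protein and globin genes were treated as groups. Beside a ratio, "up to" and "down to" give its furthest value among the alternatives, where that is over 1.5-fold away.

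There were 23 gene lists, of which 609 of 624 symbols were in the files. They covered NK2 and NK3 homeobox genes, cardiopharyngeal mesoderm and head muscle regulators, muscle structural genes, cardiac muscle genes, endothelin and dorsoventral arch patterning, cranial neural crest and ectomesenchyme, cartilage differentiation, and pharyngeal endoderm and pouch. Pathway lists covered hedgehog, FGF, BMP, WNT, Notch and retinoic acid. The others were Hox genes, S phase genes, G2 and M phase genes, p53 response and apoptosis, dissociation stress and immediate early genes, heat shock and chaperone genes, extracellular matrix and adhesion genes, globin genes, and glycolysis and hypoxia genes. Members with at least 20 UMIs in the class were used. A list's median log2 ratio was placed among 10000 random lists of the same size matched on mean expression in 20 bins, when at least 5 members were measured. Members at 1.5-fold or more were counted in each direction. Members with 0 UMIs in 1 library entered at the bound from the floor. These percentiles describe the 2 libraries only.

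For shares of cells with a UMI, every cell was thinned at random to 2000 UMIs and shallower cells were left out. Neural 2, a class of differentiated neurons, was the background for free RNA. An own Leiden clustering of both libraries together used 2000 variable genes, 30 components, 20 neighbours and a resolution of 1.0, with clusters named from at least 4 marker hits. It was repeated without the arch patterning list, although the naming of clusters still used all marker genes. Sub-clusters of the main classes used 15 components and a resolution of 0.6, were formed without the compared genes, and needed 15 cells per library. Chromosomes came from the RefSeq annotation of the GRCz12tu assembly, in which 15377 of 17075 measured symbols were found.

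Other settings fixed in advance were median-of-ratios scaling, totals without mitochondrially encoded, ribosomal protein and globin genes, all barcodes, the mean of each cell's CPM, removal of the 5% of cells with the most UMIs, cells thinned to 2000 UMIs, list minimums of 100 UMIs or of 1 UMI in each library, thinning to 1000 UMIs or none, a cell minimum of 2000 UMIs, another denominator, own clusters, and a minimum of 200 UMIs for named genes. Settings chosen after seeing the data were the clustering without the arch patterning list and the weighting of sub-clusters as in the wild-type library. On simulated data with known ratios, 95.4% of 17081 intervals over all kept cells held the true value, and 24 of the 24 top-ranked genes were genes given a difference. The simulated counts were Poisson sums per class, with no spread between cells or embryos. They check the calculation only, and real intervals can be too narrow where few cells hold most UMIs of a gene. Of 40 lists with no difference given, 4 in crest, 3 in cluster 2, 1 in cluster 7 and 0 over all kept cells fell outside the central 95% range, where 2 are expected, so percentiles near its limits may be too extreme.

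Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, python-igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9. The 116 wild-type and 69 mutant barcodes absent from the deposited cell table entered only the all-barcode alternatives and the check of such barcodes in the closing part.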

Results

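Single-cell transcriptomes were compared between 1 wild-type and 1 nkx2.7-/- library of dissected zebrafish pharyngeal arches at 26 hours post fertilization. The wild-type library held 7230 kept cells with 112704852 UMIs, and the mutant library held 4917 kept cells with 85511618 UMIs. Median depth was 12745.5 UMIs and 2673.5 genes per wild-type cell, against 13964 UMIs and 2884 genes per mutant cell. Median mitochondrial shares were 0.689% and 0.658%. The question was which arch cell populations and transcripts differ when nkx2.7, an NK-class homeobox transcription factor gene of the pharyngeal region, is mutated. Each genotype has 1 library of 2 embryos, so every difference below is between these 2 pools.

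Transcripts of nkx2.7 itself (ENSDARG00000021232) were present in both libraries, mainly in cluster 7 (deposited as pharyngeal endoderm) and cluster 2 (deposited as pharyngeal mesenchyme). Cluster 7 held 66.0% of the gene's UMIs in the wild-type library and 74.3% in the mutant library. Over all kept cells there were 235 and 222 UMIs, or 2.09 CPM (95% interval 1.83 to 2.37) and 2.60 CPM (2.27 to 2.96), a mutant to wild-type ratio of 1.25 (1.03 to 1.5). In cluster 7 the levels were 17.0 CPM (14.4 to 19.9) and 30.7 CPM (26.2 to 35.8), a ratio of 1.81 (1.44 to 2.27). In cluster 2 the ratio was 0.946 (0.618 to 1.44), or 0.322 after thinning. Cranial neural crest had 3 and 0 UMIs of the gene. In cluster 7, 40 of 493 wild-type cells (8.11%) and 31 of 239 mutant cells (12.97%) had a UMI. After thinning to 2000 UMIs these were 18 of 426 cells (4.23%, 67 left out) and 7 of 218 (3.21%, 21 left out), from median depths of 20828 and 23536 UMIs. The background class Neural 2 had 0 of 972 and 0 of 736 thinned cells, from median depths of 9731.5 and 11988 UMIs, which allows shares of up to 0.309% and 0.408%. The thinned level over all kept cells had the opposite direction, a ratio of 0.516 (0.782 in cluster 7), and lies near that of 1 UMI per positive cell, so no difference is read from it. A 3′ tag need not cover the mutated part of the gene, so these levels do not check the genotype label.

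The next comparison asks whether the cell populations of the arches took a different share of the mutant library. Arch neural crest, the source of the jaw and gill skeleton, made up nearly equal shares of both libraries, and so did cluster 2. Cluster 7, which is led by epidermal genes, took a smaller share of the mutant library. All cells came through the same sort for live nucleated cells. In clusters formed without the arch patterning genes, crest-like cells were 9.86% (9.18 to 10.6) of wild-type and 9.76% (8.95 to 10.6) of mutant cells. The naming of these clusters still used some of those genes. The deposited crest class, some of whose leading genes differ between the libraries, gave 8.88% (8.23 to 9.56) and 8.87% (8.09 to 9.70). Cluster 2 took 14.29% (13.49 to 15.12) and 15.01% (14.02 to 16.04). Cluster 7 took 6.82% (6.25 to 7.42) and 4.86% (4.28 to 5.50), and the own clusters named from epidermal markers took 6.43% and 5.13%, or 4.07% and 3.44% when formed without the arch patterning genes. Neural cells were most of both libraries, 55.9% and 57.6%. Within them, Neural 3, led by the dorsal hindbrain genes atoh1a and olig3, took 12.0% and 8.46%, whereas Neural 2 took 14.1% and 16.3%, and neural classes went both ways. Among small classes, muscle had 14 and 34 cells, the myeloid class 42 and 12 and the erythroid class 38 and 48. The class deposited as periderm had 127 and 45 cells and is led mainly by hatching gland genes. In the own clusters, one led by he1.1 and ctslb had 59 and 3 cells and one with icn2, krt17 and krt5 among its leading genes 68 and 41. Own clusters with lens markers had 22 and 49 cells.

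**Figure D1:**
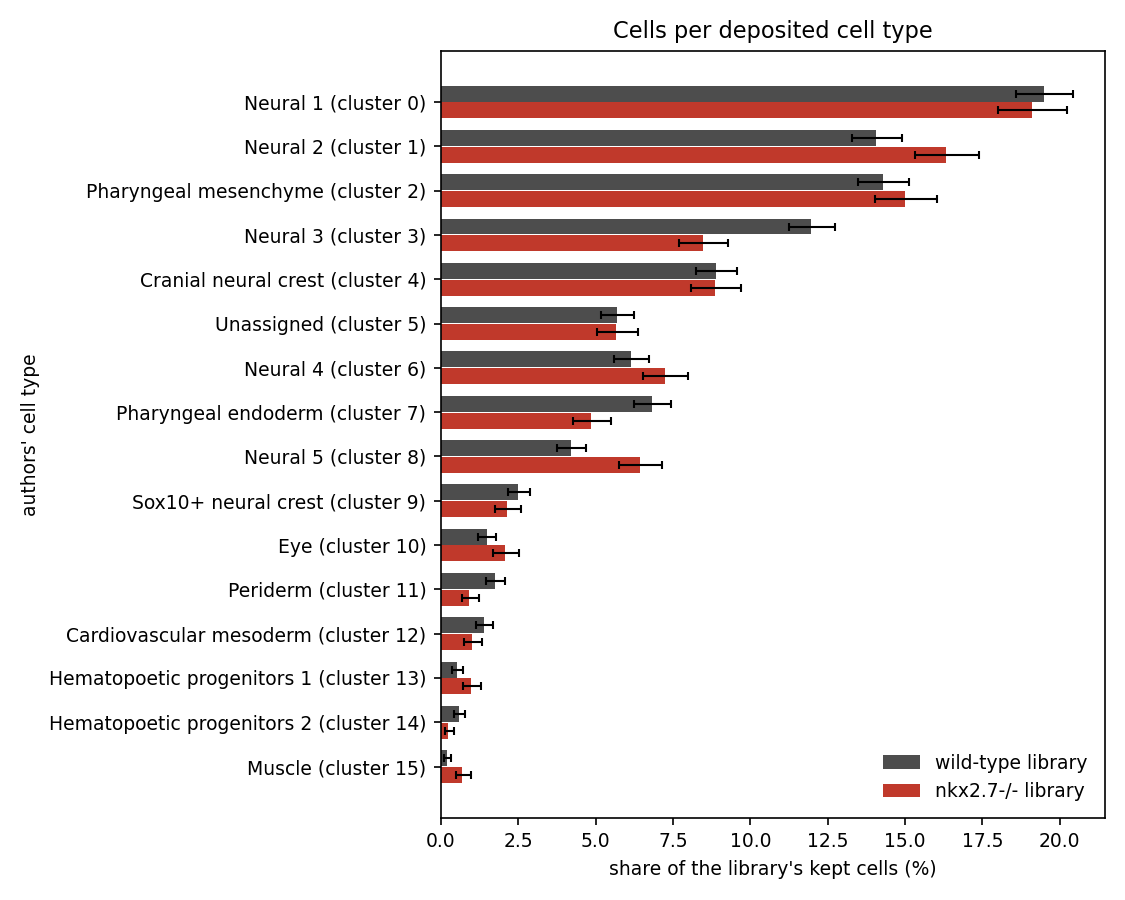
Share of each library's kept cells (%) in the 16 deposited cell types, with exact binomial 95% intervals for counting error as bars. Cranial neural crest takes 8.88% and 8.87%, and cluster 7 takes 6.82% and 4.86%.

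The main comparison was within cranial neural crest, where arch identity along the dorsoventral axis is set by endothelin signalling and its targets. Transcripts of 7 genes of the ventral and intermediate arch program were lower in the mutant library: the distal-less genes dlx3b, dlx4a, dlx4b, dlx5a and dlx6a, the ventral regulator hand2, and barx1, a homeobox gene of skeletal progenitors. The dorsal genes jag1b, a Notch ligand, and hey1, a Notch target, were higher, whereas the dorsal gene grem2b was lower. The pan-arch genes dlx2a and twist1a were not lower. Of 37 matrix and adhesion genes, 8 were at least 1.5-fold higher and 4 at least 1.5-fold lower, and the chemokine receptor gene cxcr4a was higher. The class held 642 wild-type and 436 mutant cells, with 14375858 and 9260759 UMIs.

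Among these 7 genes the lowest ratio in crest was that of dlx4a, with 1113 and 64 UMIs, 77.4 and 6.91 CPM, a ratio of 0.0893 (0.0683 to 0.115). The gene dlx3b had 3866 and 1039 UMIs, a ratio of 0.417 (0.389 to 0.447), and dlx4b a ratio of 0.593 (0.536 to 0.655). The linked pair dlx5a and dlx6a had ratios of 0.402 (0.380 to 0.426) and 0.323 (0.290 to 0.36), with dlx5a at 407.4 and 163.8 CPM. The ratio of hand2 was 0.471 (0.422 to 0.524), with 1444 and 438 UMIs. Across 5 crest sub-clusters the hand2 ratio ran from 0.0962 to 1.08. One sub-cluster, of 104 and 56 cells, had prdm1a and fgf10a among its leading genes. Both are on the marker list of lateral plate or fin mesenchyme, as is hand2. Part of the class and of its hand2 UMIs may thus not be ventral arch crest, which was not tested. For barx1 the ratio was 0.452 (0.418 to 0.489). The ventral BMP target msx1b had a ratio of 0.370 (0.277 to 0.489). Several of these genes lead the deposited class, so the same ratios were taken in crest-like clusters formed without the whole arch patterning list, of 713 and 480 cells. These clusters were still named from marker genes, among them dlx3b, dlx4b, dlx5a, dlx6a, barx1 and hand2. The check is thus not independent of those genes. In these clusters the ratios were 0.0895 for dlx4a, 0.316 for dlx6a, 0.391 for dlx5a, 0.405 for dlx3b, 0.440 for barx1, 0.469 for hand2 and 0.574 for dlx4b. Each of these 7 genes was below 1 under all 7 alternatives run for it.

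For jag1b the ratio was 1.80 (1.59 to 2.03) and for hey1 1.86 (1.59 to 2.18). The nuclear receptor gene nr2f5, which marks the upper jaw domain, had a ratio of 1.51 (1.41 to 1.63), while that of the BMP antagonist gene grem2b was 0.726 (0.689 to 0.764). For dlx2a the ratio was 1.01 (0.954 to 1.07), and for the endothelin receptor gene ednraa it was 1.1 (0.988 to 1.23). The ratio of twist1a was 1.33 (1.28 to 1.37). This gene leads the class and was left out only of the sub-clusters, which gave 1.27 when weighted as in wild-type. The genes nr2f5, grem2b, dlx2a and ednraa fall outside the naming rule and were chosen after their values were seen.

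**Figure D2:**
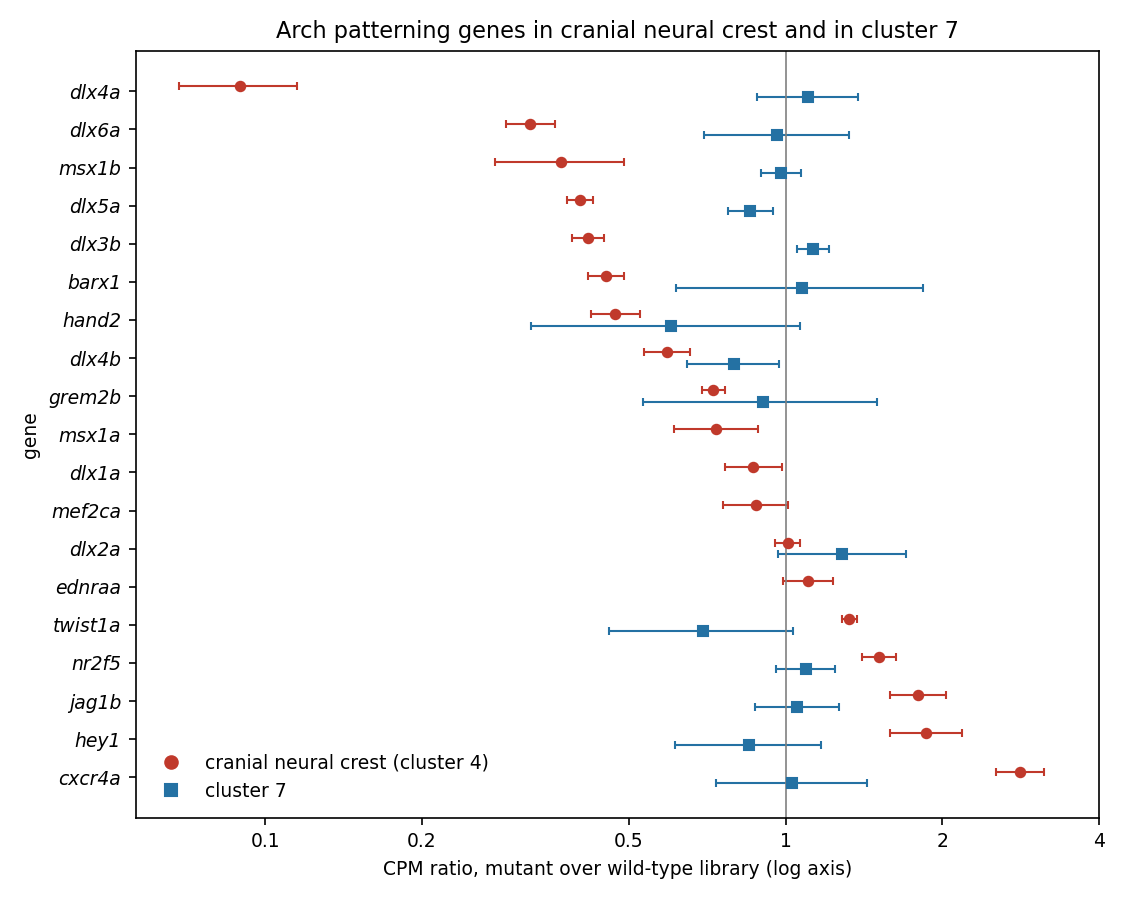
Mutant to wild-type CPM ratio (log axis) of 19 arch genes with exact 95% intervals for counting error, in cranial neural crest (circles) and cluster 7 (squares), for genes with at least 50 UMIs. In crest dlx4a lies at 0.0893 and dlx5a at 0.402, whereas in cluster 7 dlx4a lies at 1.1 and dlx5a at 0.856.

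Other named crest genes that were lower in the mutant library were cbx7a, a Polycomb subunit gene, with a ratio of 0.414 (0.368 to 0.464), and the secreted factor gene metrnla at 0.521. The cadherin gene cdh6 was at 0.622, the selenoprotein gene selenoh at 0.685 and the replication termination factor gene rtf2 at 0.670. Among crest genes named by rank, the highest ratio was that of cxcr4a, 2.82 (2.54 to 3.14), whose ligand gene cxcl12b was also higher, at 1.62. The transcription factor gene sox4a had a ratio of 2.11, the BMP target id3 1.58, and the secreted neurotrophic gene ndnf 1.72. The higher matrix genes named by the rule were periostin (postnb) at 1.88 (1.79 to 1.98), tenascin (tnc) at 1.64 and collagen col1a2 at 1.57. With sub-clusters weighted as in wild-type they were at 1.70, 1.43 and 1.37. By counting interval postnb was higher in 4 and lower in 1 of 5 sub-clusters, and col1a2 higher in 3 and lower in 1. A sub-cluster with tnn and col1a1a among its leading genes held 16.5% (13.7 to 19.6) of wild-type and 27.5% (23.4 to 32.0) of mutant crest cells. The other higher genes were the chaperone gene hsp90aa1.2 at 1.65, the linker histone gene histh1l at 1.5 and the nucleotide hydrolase gene dnph1 at 1.61. Of these, selenoh, rtf2 and histh1l were shifted the same way in 11 of 11 compared classes, so they are not specific to crest.

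The share of crest cells with a UMI was read after thinning to 2000 UMIs, in 625 wild-type and 416 mutant cells with 17 and 20 left out and median depths of 22339 and 21856 UMIs before thinning. Cells with hand2 were 14.6% (11.9 to 17.6) of the wild-type and 5.53% (3.54 to 8.18) of the mutant library, and unthinned shares were 25.2% and 11.2%. For dlx5a the shares were 36.8% and 17.3%, unthinned 60.4% and 38.1%. For dlx3b they were 31.8% and 16.1%, for barx1 23.8% and 12.3%, for dlx6a 17.9% and 6.97%, and for dlx4a 10.6% and 1.2%. Shares were higher in the mutant library for jag1b, 5.12% and 11.8%, and for cxcr4a, 7.36% and 17.8%. The background class Neural 2 had hand2 and cxcr4a in 0% of thinned cells, dlx4a in 0.103% and 0.136%, barx1 in 0.309% and 0.272%, and jag1b in 1.03% and 1.22%. It had dlx3b in 0.823% and 0.272%. For dlx5a it had 7.10% and 6.25%, and for dlx6a 2.78% and 2.17%, genes that forebrain neurons also express.

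**Figure D3:**
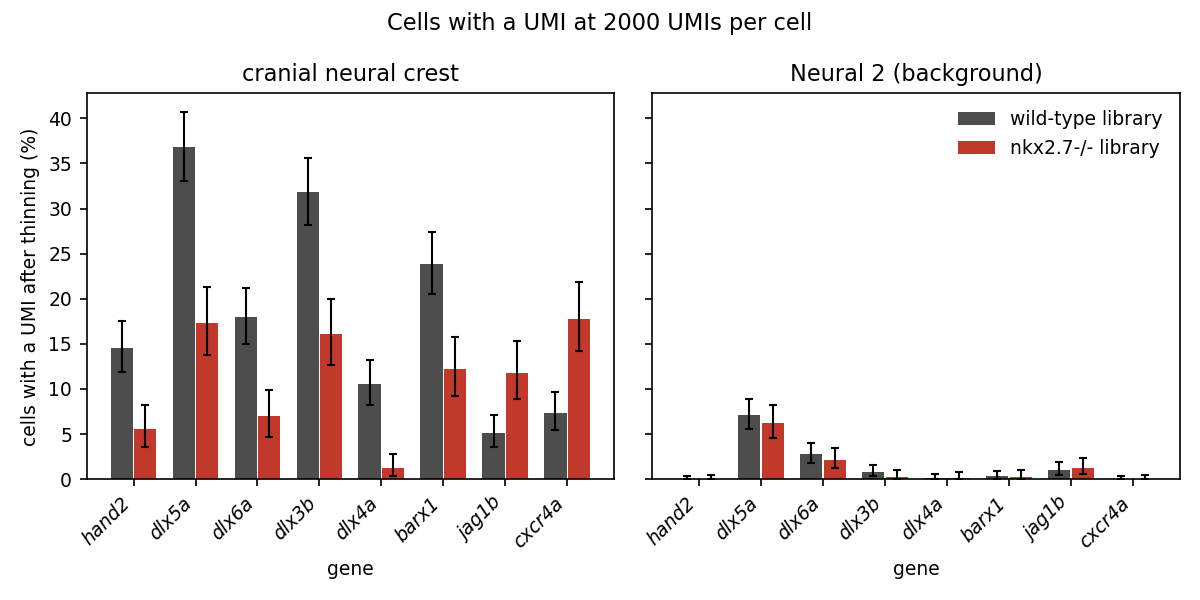
Share of cells (%) with at least 1 UMI of each gene after thinning to 2000 UMIs per cell, in cranial neural crest and in the background class Neural 2, with exact binomial 95% intervals as bars. In crest hand2 is in 14.6% of wild-type and 5.53% of mutant cells.

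As whole lists, the arch patterning genes split in crest: of 33 measured, 9 were at least 1.5-fold lower and 3 at least 1.5-fold higher, with a median log2 ratio of -0.04 at percentile 1.48 of matched random lists, a median that turns to 0.023 without the 5% of deepest cells and to 0.057 after thinning. Cartilage genes had a median of -0.24 (17 measured, 4 lower and 0 higher, percentile 0.01), a median that comes to about 0 without the 5% of deepest cells. Their collagen col2a1a, at 0.522, was at 1.00 without those cells. Neural crest and ectomesenchyme genes had a median of 0.28 (percentile 100), with cdh11 at 1.35 and foxc1b at 1.36. Matrix and adhesion genes had a median of 0.24 (percentile 100) and cardiopharyngeal regulators 0.31 (99.98), among them eya1 at 1.88. The hedgehog list was at 0.23 (99.2), with foxf2a at 1.86 and foxd2 at 1.76. The FGF list was at 0.17 (96.6), WNT at 0.11 (73.5), Notch at 0.10 (74.0), BMP at 0.08 (69.6) and retinoic acid at -0.06 (3.28). The secreted WNT antagonists diverged, sfrp5 at 1.90 and sfrp2 at 0.679, and the BMP antagonist gene nog1 was at 1.68. Endoderm and pouch genes measured in crest were at 0.57, with six1b at 1.36. Glycolysis genes were at -0.20 (percentile 0), or 0.0645 as a mean over cells, with gapdhs at 0.478, and heat shock genes at 0.21 (99.9). S phase genes were at 0.06 (94.0) and G2 and M phase genes at -0.06 (0.08), with 0 members of either list at 1.5-fold or more, and the G2 and M phase median was 0.067 without the 5% of deepest cells. The p53 and apoptosis list was at 0.07, immediate early genes at 0.05, Hox genes at 0.16, ribosomal protein genes at -0.01 and mitochondrially encoded genes at 0.11. The lists furthest from 0 in crest were those of other cell types, muscle structural genes at 1.65 (14 of 16 higher and 1 lower, percentile 100) and globin genes at 1.66 (8 of 8 higher, percentile 100). Globin medians were above 0 in each of the 11 compared classes, from 0.49 to 1.66. No NK2 or NK3 gene and 3 cardiac muscle genes reached 20 UMIs in crest, too few to rank.

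**Figure D4:**
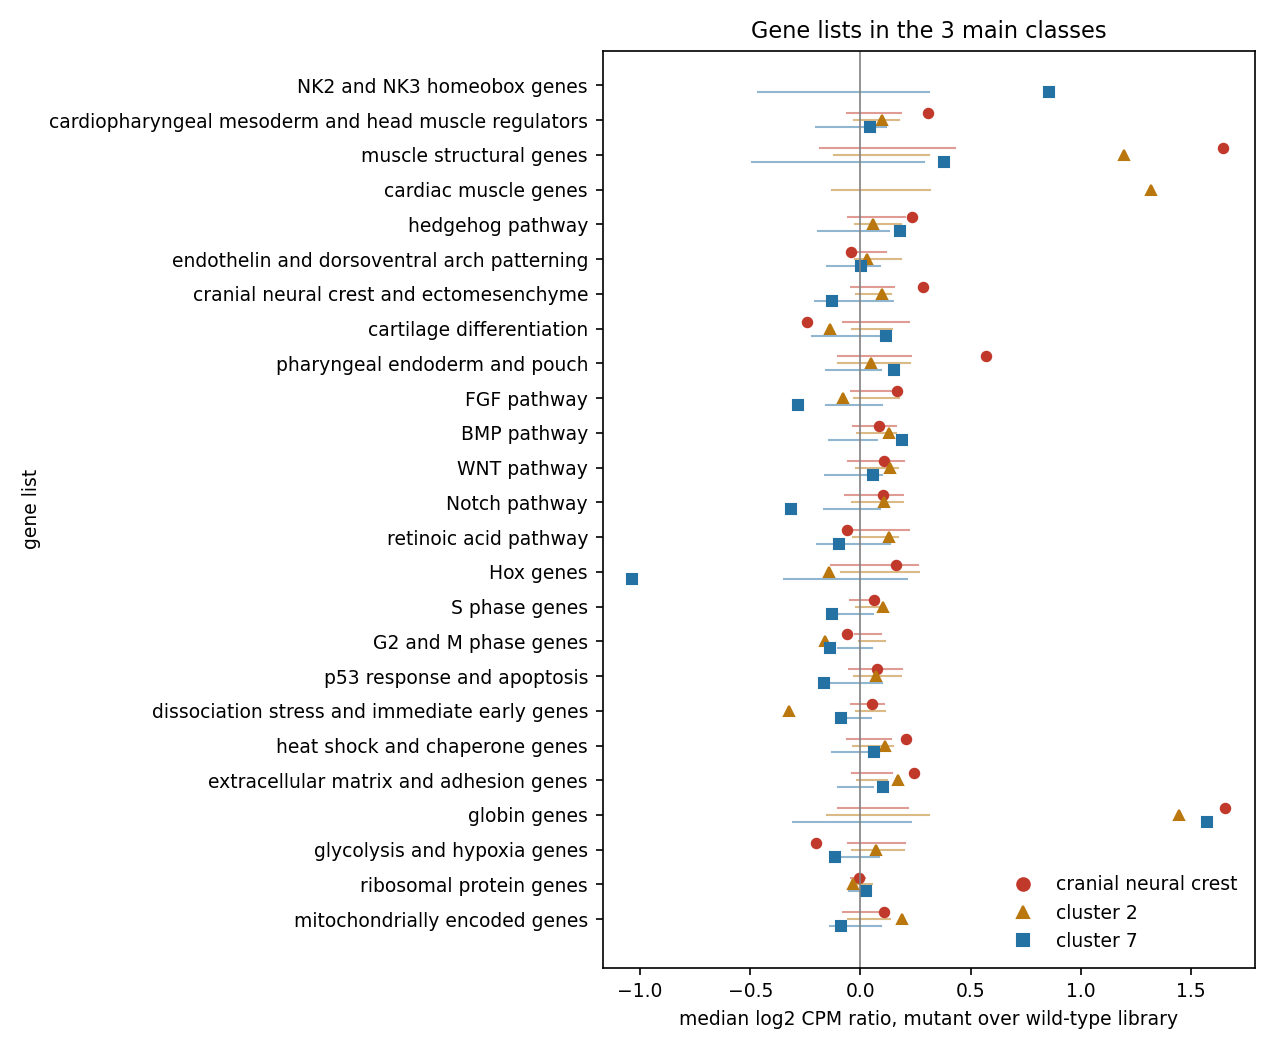
Median log2 CPM ratio of the 23 gene lists and 2 gene groups in cranial neural crest, cluster 2 and cluster 7 (markers), over the central 95% range of matched random lists (lines), for lists with at least 5 measured members. The Hox list lies at -1.04 in cluster 7, at 0.16 in crest and at -0.14 in cluster 2.

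Cluster 2 was compared for genes of the mesoderm and mesenchyme around the arches. It is a mixed class led by the cartilage and sclerotome genes col2a1a, col9a2 and meox1. The signalling genes edn1 and shha had lower levels in the mutant library, as did 6 of 32 immediate early genes. Of 12 cardiac muscle genes 9 had higher levels, and so had 14 of 19 skeletal muscle and 7 of 7 globin genes. Of 28 cardiopharyngeal regulators 6 were higher and 1 lower, with a list median of 0.098 (percentile 70.7). The gene tcf21, whose reporter guided the dissection, was lower, with 414 and 233 UMIs in 93 and 48 cells. Its ratio was 0.710 (0.602 to 0.835), while that of tbx1 was 1.002. Both genes fall outside the naming rule and were chosen after their values were seen. The endothelin ligand gene edn1, the upstream signal of the ventral arch program, had 98 and 27 UMIs in 21 and 13 cells, a ratio of 0.347 (0.218 to 0.536; down to 0.207), and shha, the hedgehog ligand gene of the pharyngeal epithelium, had 88 and 7 UMIs in 15 and 4 cells, a ratio of 0.10 (0.0392 to 0.215; 0.0456 to 0.170 over the alternatives). The endodermal gene foxa1, at 0.414, and the epithelial gene epcam, at 0.511 (up to 0.901 among the alternatives), shared that direction. Over all kept cells, however, shha was at 1.02 (0.941 to 1.098) and edn1 at 0.837 (0.655 to 1.07). Most of the 1513 and 1167 shha UMIs were in neural classes, with 828 and 655 in Neural 1 and 356 and 257 in Neural 4. The shha ratio over all kept cells is thus mainly a neural value and does not describe the pharyngeal epithelium. In cluster 7, shha was at 1.395 (0.958 to 2.02) and edn1 at 2.32.

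Among cluster 2 genes named by rank, high ratios were those of the metalloproteinase inhibitor gene timp2b, 3.01 (2.73 to 3.34), and of cbx7a, 2.43 (2.29 to 2.58), the reverse of its ratio in crest. The matrix protein genes vwde and col5a2a were at 1.95 and 1.71, the cyclin gene ccnd1 at 1.66, the mitochondrial import gene timm8b at 1.73 and the membrane protein gene plp2 at 1.68. The forkhead gene foxd2 was at 1.52, the actin regulator gene arpc5a at 1.55, the glycolysis gene tpi1b at 1.58 and the tight junction gene cldn11a at 1.58. Lower ratios were those of sh3bgrl2 at 0.381, the glutathione transferase gene gstt1a at 0.402, the retinoic acid receptor gene raraa at 0.503 and the matrix genes thbs4b and ccdc80l1 at 0.528 and 0.545. The stress response genes jdp2b and atf3 were at 0.555 and 0.556, fosl1a at 0.576 and fosb at 0.582. The cell cycle gene ccng2 was at 0.582, the coagulation gene f3b at 0.577 and rtf2 at 0.573. Shifts in the same direction were also seen for rtf2 in 11 of 11 compared classes, timm8b in 10 of 11, arpc5a in 9 of 11, and plp2 and raraa in 9 of 9 with enough UMIs.

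The dissociation stress and immediate early list in cluster 2 had a median of -0.32 (percentile 0, 6 of 32 lower and 1 higher), with junba at 0.673. The FGF list had -0.08 (0.215), a direction that turns as a mean over cells (0.022) and after thinning (0.053), with the feedback genes dusp2 and spry2 at 0.510 and 0.597. Cardiac muscle genes had a median of 1.32 (9 of 12 higher), with myh7 at 5.64 (3.26 to 6.76 over the alternatives) and tnnt2a at 5.56 (4.21 to 14.5). The cardiac regulator gene nkx2.5 was at 1.73 (1.2 to 2.5), from 12 and 13 cells, and hand2 at 2.62 (1.86 to 3.74), from 15 and 12 cells. For each of myh7, tnnt2a and hand2, only 1 of 9 sub-clusters held at least 20 UMIs. For nkx2.5, 3 did, with ratios from 0.248 to 4.67. By counting interval nkx2.5 was lower in 1 and higher in 2 of them. Muscle structural genes had a median of 1.2 (14 of 19 higher and 1 lower, percentile 100) and globin genes 1.45 (7 of 7 higher, percentile 100). Matrix genes had 0.17 (99.97), with fn1b at 3.33 (down to 1.57), col6a3 at 1.99 and col4a1 at 1.84. The Hox genes hoxb8a and hoxc8a were at 6.98 and 8.47 (up to 11.6 and 16.0), although the Hox list's median was -0.14 (5 higher and 7 lower of 21), or 0.53 after thinning. The crest genes pax7a and tfap2a were at 1.97 and 1.78 (tfap2a up to 2.81), the cartilage regulator gene runx3 at 0.125 and the retinoic acid hydroxylase gene cyp26b1 at 2.02. G2 and M phase genes had -0.16, with nusap1 at 0.767 and cdk1 at 0.787.

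Cluster 7 was compared because pharyngeal endoderm was among the main classes set in advance. Most UMIs of nkx2.7 and nkx2.3 were in this class, but edn1 had 98 wild-type UMIs in cluster 2 against 41 in cluster 7. Cluster 7 is led by epidermal keratin and claudin genes, and none of its leading genes is on the endoderm list. The paralogue nkx2.3 and edn1 had higher levels in the mutant library. Lower levels were those of the 3 keratin genes named below, 6 of 11 Hox genes and 9 of 25 Notch genes, with 0 Hox and 1 Notch gene higher. The ventral arch genes that were low in crest were near equal here, with a median ratio of 0.965 (0.602 to 1.13) over the same 7 genes. The ratio of nkx2.3 was 1.77 (1.53 to 2.04), and that of edn1 2.32 (1.52 to 3.56; up to 3.70) from 41 and 56 UMIs in 21 and 14 cells. The growth factor genes fgf3 and fgf8a were at 0.20 (0.0701 to 0.466) and 0.437 (fgf8a down to 0.279), with fgf3 at 0.447 as a mean over cells. The endodermal transcription factor gene gata6 had 55 and 2 UMIs, a ratio of 0.0618 (0.0073 to 0.234), or 0.326 after thinning. Of 45 cluster 7 genes run under the alternatives, 24 moved by over 1.5-fold in at least 1 of them.

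Higher named genes of cluster 7 included the secreted factor gene ecrg4b at 3.85 (3.62 to 4.1), tnc at 3.21, the sulfotransferase gene sult1st1 at 2.53 (up to 3.98) and the disulfide isomerase gene agr2 at 2.21. For agr2, 1 cell held 33.0% of the wild-type and 1 cell 47.2% of the mutant UMIs, and the ratio was 1.18 without the 5% of deepest cells. The chemokine genes cxcl12a and cxcl12b were at 2.32 and 2.13, the otolith gene stm at 2.14, the protease gene prss35 at 2.24 (down to 1.45), plp2 at 1.90 and the ephrin gene efnb2a at 1.81. The metallothionein gene mt2 was at 6.18, but 1 cell held 83.5% of its wild-type UMIs. Lower named genes were the matrix protease genes mmp13a at 0.105 (0.0776 to 0.139; up to 0.171) and mmp9 at 0.450 (but 0.927 as a mean over cells), the hatching enzyme gene he1.1 at 0.197, the complement gene cfd at 0.346 (up to 0.606) and the phosphatase gene dusp5 at 0.388. The keratin genes krt17, krt15 and krtt1c19e were at 0.407, 0.421 and 0.453 (krt15 0.274 to 0.644 over the alternatives), hopx at 0.400 (up to 0.617) and nccrp1 at 0.456. Fibronectin fn1b was at 0.415, but at 1.06 as a mean over cells, and fn1a was at 0.473. The ratio of he1.1 was lower in 11 of 11 compared classes, with a median of 0.199, and efnb2a was higher in 9 of 11, so neither is specific to cluster 7.

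By list, cluster 7 had NK2 and NK3 genes at a median of 0.86 (6 of 7 higher) and Hox genes at -1.04 (6 of 11 lower, percentile 0), with hoxb1b at 0.148 (0.0790 to 0.255; up to 0.227), hoxb3a at 0.365 and hoxa4a at 0.488 (down to 0.217). The Hox list was also at -0.70 in Neural 1, -1.18 in Neural 4, -0.53 in the eye class and, from 4 genes, -1.95 in Neural 5. In crest, by contrast, its median was higher in the mutant library. The Notch list had -0.32 (0.03), with her4.1 at 0.196, her12 at 0.257 (down to 0.0928) and dlb at 0.587 (down to 0.36), and the FGF list -0.28 (0.06). The BMP list had 0.19 (99.97), with bmp2b at 1.65, a direction that bmp2b and its list lose after thinning. Endoderm and pouch genes had 0.15 (99.8), or -0.21 after thinning. Muscle structural genes had 0.38 (4 of 11 higher and 1 lower, 99.1) and globin genes 1.57 (7 of 7 higher, 100). The retinoic acid hydroxylase gene cyp26c1 was at 2.43 and shhb at 3.3 (down to 1.47). The immediate early list had -0.09, or 0.076 as a mean over cells, with egr3 at 0.460 (down to 0.186) and nr4a1 at 0.503 (down to 0.333).

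Over all kept cells, the highest ratios belonged to fast skeletal muscle genes and the lowest to hatching gland, myeloid, pigment and epidermal genes. The pools held 14 and 34 muscle cells and 42 and 12 myeloid cells. The ventral gene dlx5a was also among the 12 lowest, at 0.528 (0.508 to 0.549). Muscle structural genes were higher for 27 of 27 members, a median of 2.21, with mylpfa at 6.35 (6.22 to 6.49), pvalb1 at 6.14, myhz1.1 at 6.05, myhz1.3 at 5.79, tnnt3b at 5.64 and pvalb2 at 5.40. The genes mylz3, myl1, ttn.2, ckmb and ttn.1 were between 5.25 and 4.63. Over the alternatives mylpfa reached 9.80, myhz1.1 11.3 and myhz1.3 11.9, ckmb was as low as 2.57, and ttn.2 and ttn.1 ran from 3.26 to 8.23 and from 2.95 to 7.47. The lens gene crybb1 was at 5.68 (down to 3.31). Among the lowest were the hatching enzyme genes he1.2 at 0.20 and he1.1 at 0.232 and the protease gene ctslb at 0.19, for which 1 cell held 92.8%, 94.3% and 91.7% of the mutant UMIs (down to 0.113, 0.104 and 0.123). The pigment gene gch2, with 48.2% of mutant UMIs in 1 cell, was at 0.212 (0.119 to 0.469 over the alternatives), pvalb8, a leading gene of cluster 7, at 0.285 (up to 0.451) and the keratin gene krtt1c19e at 0.392. The myeloid genes lyz, srgn and cst14b.2 were at 0.372, 0.403 and 0.321 (up to 0.634, 0.692 and 0.531), cebpb at 0.495 and tcnbb at 0.530.

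Of the lists over all kept cells, NK2 and NK3 genes had a median of 0.53, with the forebrain gene nkx2.4b at 1.52 and nkx2.2a at 1.5. Arch patterning genes had -0.02, or 0.097 as a mean over cells (0 higher and 7 lower of 35), with dlx4a at 0.245, barx1 at 0.397, dlx6a at 0.439 and hand2 at 0.480. Cardiac muscle genes had 0.49, with myh6 at 3.94 (up to 6.38) and actc1a at 4.31 (1.59 without the 5% of deepest cells), and globin genes 0.81, with hbae5 at 4.98 and hbbe2 at 2.11 (up to 9.41 and 5.80). The dissociation stress and immediate early list had -0.16 (percentile 0), against 0.55 in Neural 5 and 0.29 in the eye class, both at percentile 100, with egr3 at 0.534 and nr4a1 at 0.568. Heat shock genes had 0.07, with hsp70.2 at 2.74 and the muscle chaperone gene hsp90aa1.1 at 3.86 (1.27 without the 5% of deepest cells). Retinoic acid genes had 0.00, with aldh1a2 at 1.69 and raraa at 0.540, and FGF genes -0.03, or 0.109 as a mean over cells and 0.034 after thinning, with dusp2 at 0.543. Hox genes had -0.13, with hoxc8a at 5.05 (down to 2.58) and hoxb8a at 2.00. The Notch target her12 was at 0.640, cxcr4a at 2.00, myod1 at 2.91 (up to 4.52), fn1b at 0.433 (up to 0.862) and myhz2 at 13.1 (9.77 to 18.0; down to 7.02).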

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

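The tests of the ventral genes, of the muscle transcripts and of the genes shifted in most classes were chosen only after the results were seen. The test of the named genes against the chromosome of nkx2.7 was not.

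The ventral arch genes dlx3b, dlx4a, dlx4b, dlx5a, dlx6a, barx1 and hand2 were lower in mutant crest, with a median ratio of 0.417. Weighting the crest sub-clusters as in wild-type left a median of 0.440 (highest 0.665), which argues against another mix of these sub-clusters as the whole cause. The sub-clusters were formed without the arch patterning genes and need not separate ventral from dorsal crest. A changed share of ventral crest is therefore not tested by this weighting. By counting interval, dlx5a was lower in 5 of 5 sub-clusters and dlx4a in 4 of 4, but hand2 and barx1 in 3 of 5, and dlx4b was higher in 1 of 4. The tables also argue against a haplotype linked to nkx2.7 acting on the genes themselves, since 0 of the 7 lie on chromosome 8. They also argue against a loss in all cells, with a median of 0.965 (0.602 to 1.13) in cluster 7 and dlx5a at 0.891 in Neural 2, although at lower counts dlx3b and dlx5a were 0.196 and 0.145 in the Unassigned class, dlx3b and barx1 0.388 and 0.240 in Neural 2, and dlx5a and barx1 0.126 and 0.620 in cluster 2. Fewer ventral cells and a lower level per cell cannot be told apart: in the 162 and 49 crest cells with a hand2 UMI the median of the 5 dlx genes was 0.557 (0.276 to 0.836), but hand2 is itself among the lower genes. With 1 pool of 2 embryos per genotype, a difference in stage, dissection or parentage between the pools stays open and untested, as does the genotype itself.

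Muscle transcripts were higher in mutant cells of classes other than muscle. Free RNA from muscle cells may be the source: over 8 fast muscle genes, which the muscle cells of the dissected tissue also express, mutant cells had a median of 0.438 UMIs per cell across 15 other classes, 13 of which lay within 2-fold of it, and 15 of 15 were higher than in wild-type. The mix of these 8 transcripts overlapped that of muscle cells by 89.2%, and mutant muscle cells held 5538 UMIs of them per cell. The sort on viability does not remove muscle cells. More trunk tissue in the mutant pool cannot be told apart from this: Hox genes of groups 6 to 9 had a median ratio of 1.56 (6 of 8 higher) and 16 genes of groups 1 to 5 had 0.703, but each genotype has only 1 dissection.

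Some genes were shifted in 1 direction, by a median of at least 1.25-fold, in at least 7 of the 11 compared classes and all but at most 2 of those where they were measured, 33 higher and 19 lower in the mutant library. Of these 52 genes 25% (13) lie on chromosome 8 with nkx2.7, against an upper limit of 9.62% of the central 95% of random sets matched on expression, and of the 87 named genes 9.20% (8) do, against 8.05%, so a haplotype carried along with the mutant allele may account for part of them. Among measured genes, 7.69% of the 65 nearest to nkx2.7 were shifted, 4.1% of the rest of chromosome 8 and 0.652% of other chromosomes, and examples on chromosome 8 are cxxc1a at 0.261, ogg1 at 3.33, plp2 at 1.90 and selenoh at 0.715. Free RNA of muscle, hatching gland and myeloid cells as the main source is argued against, since 4 of the 52 genes are such transcripts. The 39 shifted genes elsewhere stay open, as variants that differ between the pools and effects of the genotype were not tested.

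Of the named genes, 5 had opposite directions in 2 main classes, each past 1.5-fold by its counting interval, and the differences between classes were not tested. The ratio for cbx7a was 2.43 in cluster 2 and 0.414 in crest, 5.88 times apart, and for hand2 it was 2.62 in cluster 2 and 0.471 in crest, 5.57 times apart, with the UMIs of cluster 2 in 15 and 12 cells only. The ratio for edn1 was 2.32 in cluster 7 and 0.347 in cluster 2, 6.68 times apart. For fn1b the ratios were 3.33 in cluster 2 and 0.415 in cluster 7, 8.03 times apart, although as a mean over cells the latter was 1.06. For cfd they were 61.8 (10.6 to 2489; up to 113.7) in cluster 2, from 1 and 49 UMIs, and 0.346 in cluster 7, 178.3 times apart.

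The barcodes absent from the deposited cell table include 2 of the mutant library with a low mitochondrial share and a high depth. One had 128362 UMIs, 8076 genes and 0.371% mitochondrial UMIs, and the other 103210 UMIs, 8155 genes and 0.712%. The deepest kept mutant cell had 128550 UMIs, and the other 67 absent mutant barcodes had at least 20% mitochondrial UMIs. Both barcodes entered the all-barcode alternatives and no other comparison.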

How the results depend on the processing

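In this part, the tests chosen only after the results were seen were the clustering without the arch patterning list, the expression ratios taken in it, and the weighting of sub-clusters as in the wild-type library. No paired analysis was possible because each genotype has 1 library. The lower ventral genes of cranial neural crest kept their direction under all 7 alternatives run for them, with ratios of 0.0760 to 0.112 for dlx4a, 0.310 to 0.397 for dlx6a, 0.381 to 0.440 for dlx5a, 0.386 to 0.440 for dlx3b, 0.418 to 0.5 for barx1, 0.381 to 0.612 for hand2 and 0.547 to 0.795 for dlx4b. Every alternative kept the direction of 42 of 44 genes in crest (not col2a1a and dlx2a), 47 of 48 in cluster 2 (not nkx2.7), 42 of 45 in cluster 7 (not bmp2b, fn1b and nkx2.7) and 48 of 48 over all kept cells, nkx2.7 apart. Of 1083 expression values under alternatives, 802 stayed inside the counting interval, 276 moved and 5 reversed. Median-of-ratios scaling could not turn genes named by rank, since the rule required their direction under it. That scaling and the totals without gene groups only rescale a class. The absent barcodes hold 0.107% of wild-type and 0.361% of mutant UMIs. These settings gave 185, 185 and 48 of the 1083 values, with 0 reversed, so they test the direction little. Of 636 list medians 419 stayed, 200 moved and 17 reversed. Of 52 shares of cells with a UMI, 35 stayed and 17 moved, and of 12 shares of a class 10 stayed and 2 moved. Reversals count only values whose interval left out equality and list medians outside the central 95% of random lists, and another 2 expression values, 38 list medians, 7 shares with a UMI and 3 shares of a class also turned direction. A move of over 1.5-fold in some alternative was seen for 3 of 44 genes in crest, 11 of 48 in cluster 2, 24 of 45 in cluster 7 and 24 of 48 over all kept cells. With a minimum of 200 UMIs, the same 24 genes were named in each main class and over all kept cells. This setting could not remove a gene, since the CPM minimum of the naming rule already requires more UMIs than that. It therefore does not test the choice of named genes.

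Thinning to 2000 UMIs reversed the nkx2.7 ratio over all kept cells (0.516) and in cluster 7 (0.782), col2a1a in crest (1.88) and bmp2b in cluster 7 (0.951). It reversed the medians of the FGF list (0.034 over all kept cells, 0.053 in cluster 2), of arch patterning (0.057) and cartilage (0.0023) in crest, of Hox genes in cluster 2 (0.53), and of endoderm and pouch (-0.21), BMP (-0.066) and matrix genes (-0.025) in cluster 7. It moved dlx5a to 0.438 and hand2 to 0.381 in crest, and in cluster 2 edn1 to 0.207 and the immediate early list to -0.24. As a mean of each cell's CPM, reversed medians were those of arch patterning (0.10) and FGF (0.11) over all kept cells, glycolysis in crest (0.0645), cartilage (0.046) and FGF (0.022) in cluster 2 and immediate early genes in cluster 7 (0.076), and the ratio of fn1b in cluster 7 was 1.06. The same setting moved arch patterning in crest to -0.20 and immediate early genes in cluster 2 to -0.22. Without the 5% of deepest cells, col2a1a (1.00) and the arch patterning (0.023), cartilage (0.0038) and G2 and M phase (0.067) medians in crest reversed. Median-of-ratios scaling moved arch patterning in crest to -0.10 and immediate early genes in cluster 2 to -0.40. With members of at least 1 UMI in each library, cartilage in crest moved to -0.051. Weighting sub-clusters moved dlx5a to 0.440 and hand2 to 0.612. For all of these the cause was not tested.

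With fewer classes in the denominator, the mutant minus wild-type share moved to 2.59 points for cluster 2 and -4.47 points for cluster 7, and the cause was not tested. The hand2 share in crest differed by -3.58 points at 1000 UMIs and by -14.0 points with no thinning, since more UMIs per cell find more positive cells. That of nkx2.7 in cluster 7 differed by 4.86 points with no thinning, the opposite direction to the thinned shares, and the cause was not tested. Barcodes absent from the cell table have no class, so all-barcode values exist only over all cells. Fewer than 5 members reached 100 UMIs for 3 of 88 list medians, which have no value there. Depth limits the thinned values, which leave out 712 wild-type and 588 mutant kept cells, and the nkx2.7 shares, which rest on 18 and 7 cells in cluster 7.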

Other observations

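No test was run for the values in this part, which were chosen after the data were seen. Within cluster 7, a sub-cluster led by the lipoprotein and plasma protein genes afp4, apoa1a and apoa1b held 44 and 5 cells, 8.92% and 2.09% of the class. Its median depths were 614 and 689 UMIs, where the other sub-clusters of the class had medians of 12673.5 or more.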
